A study of Rattus norvegicus with 4 samples.

How the data were processed

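The series deposited 1 matrix of gene-by-barcode counts with its gene and barcode lists, for 4 titled samples of rat hippocampus (NC, MCAO, DEPR and MD). The values are UMI counts as the authors deposited them, whole numbers with no normalisation. Per the file headers, the matrix was written by Cell Ranger 5.0.0. The submitters' processing notes name Cell Ranger and STAR and the genome build Rnor_6.0. Per the labels' protocols, tissue was dissociated with an enzymatic kit, red cells were lysed, and libraries were made with a 10x Genomics 3' kit of version 3. The gene annotation, the settings of cell calling and any equalising of depth between libraries are not given in the sources used here. The lowest barcode total was 500 UMIs.

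The matrix held 32623 genes, 31638 barcodes and 48376980 entries above 0. Barcodes ended in 1 of 4 suffixes, and no label or file used here ties a suffix to a titled sample. The suffixes were therefore kept as 4 unassigned barcode sets. The planned differences between titled samples within each cell type were not computed, and sets were not grouped, averaged or tested. UMI totals were 43640627, 46669201, 36242408 and 54295520 in sets 1 to 4, with 1383, 1353, 1767 and 1656 genes per barcode at the median.

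Gene symbols were those of the gene list. A separate table of rat gene names, built on the assembly GRCr8, held 17249 of the 30017 distinct symbols and was used for names only. Where several genes shared a symbol (147 symbols, 2753 genes), the gene with most UMIs was used. Before the data were examined, 29 gene lists (345 entries) and 22 cell type marker lists (174 entries) were fixed, along with the tests, the rule for named genes and most alternatives. Of the list entries 13, and of the marker entries 10, matched no symbol; these genes, among them Nr3c1, Hspa1a, Pecam1, Cd36, Ccr2 and Foxj1, were not analysed here. Another 36 list genes were also markers and were left out of the list medians.

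Cells were kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs, which left 6554, 8250, 5315 and 8760 cells in sets 1 to 4. Doublets were called in each set with Scrublet at an expected share of 6%, and 220, 277, 135 and 341 cells were removed, which left 6334, 7973, 5180 and 8419. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were chosen per set and ranked over sets, leaving out list genes that are not markers. Cells were clustered with 30 principal components, 15 neighbours and the Leiden method at resolution 1 (random seed 1, Leiden as implemented in igraph), with no alignment of the sets to each other, which gave 23 clusters. The tools were scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 on Python 3.11.15, and edgeR 4.0.16 on R 4.3.3 for the factors of TMM scaling.

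A cluster was named "X-like" after the marker list with the largest share of its genes enriched, where a marker was enriched when found in at least 25% of the cluster's cells at a log2 ratio of at least 1 over all other cells, with 5 CPM added. At least 3 markers and 33.3% of the list had to be enriched. A cluster stayed unnamed when its 10 leading genes held more markers of another type than of its own, or when its UMIs per cell were low and no own marker led. It also stayed unnamed when another type's markers (those with at least 20 CPM in that type) stood at 10% or more of their level there at the median. Related types were exempt from both tests on another type's markers. The markers were fixed beforehand, and these thresholds were chosen after the data were seen. Clusters named alike were joined into 1 class, and a cluster held mostly by 1 library was not taken for a separate type. Focal clusters with a median of UMIs under 33.3% of that of all kept cells (1, 5 and 6), or with over 8% of another type's marker level (18), were called doubtful, also after the data were seen.

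Shares of cells were given per set with exact binomial (Clopper-Pearson) 95% intervals. For each focal class, UMIs were summed per set, divided by the total (CPM, counts per 1e6 UMIs) and compared with the sum of all other named cells. A gene was measured with at least 20 UMIs in the class and the rest together in every set, and was called higher or lower when the ratio was at least 2 or at most 0.5 and its exact conditional binomial 95% interval left out 1 in every set. A list was described by the median log2 ratio of its measured members and by its percentile among 10000 random lists of the same size matched on expression in 20 bins and drawn from genes that are no markers; it lay above or below when it was outside the middle 95% in every set. Between sets, a gene was measured within a class with at least 50 UMIs over the highest and lowest set together, and lay apart when their ratio was at least 2 with an interval that left out 1. For the lists between sets, markers stayed in, and the percentiles were added after the data were seen. These percentiles were high for many lists in each class, also for lists mostly within the free RNA level, such as myelin in endothelial-like and microglia-like cells (100 each). For others they were low, such as immediate early genes in endothelial-like cells (4.56). A high percentile between sets therefore does not single out a list. In a ratio, a count of 0 in a set was set to a floor of 3 counts, and such a ratio is a bound. CPM carried exact Poisson 95% intervals. With 1 library per titled sample and no set tied to one, no test across groups was possible, no p-value was computed, and the checks for a sample far from its group had no group to run on.

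The level of free RNA in a class and set was taken from the markers of the other 2 focal classes (those with at least 20 CPM in their own class and on no other marker list), as the percent of their CPM in their own class. A difference between sets was called above free RNA when it exceeded the 90th percentile of that level times the gene's highest CPM in another named class. The unnamed clusters were left out as a source, so counts above free RNA can be too high for transcripts of those clusters. By the rule fixed beforehand, the text names 2 to 4 members per list (those called with the largest and smallest median log2 ratio, then those with most UMIs), and between sets the 10 genes of largest ratio per class and the list members that lay apart. Some genes that the rule names are not reported here, while counts and list medians include them. Values are printed for part of the latter, chosen after the values were seen, and the others are named without values.

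The rules for calling genes were tested on simulated data: Poisson counts at the real totals per set and the real mean levels of 32623 genes, with 50 genes changed at each of 4 sizes. The simulation has no spread beyond counting error, and class and rest share 1 profile apart from the changed genes. It therefore could not show calls that follow from a shift of the median of all genes. Such a shift was seen in microglia-like cells, where TMM scaling kept 2715 of 3973 lower calls. For a class against the rest, 82%, 100% and 86% of 3-fold changes were recovered in endothelial-like, microglia-like and oligodendrocyte-like cells, with 0 unchanged genes called; 1.5-fold changes lie below the ratio of 2 that the rule asks for. Between sets, with 1 set changed, 98%, 100% and 100% of 3-fold changes were called apart, whatever the direction. The changed genes had at least 200 UMIs over the 4 sets, so recovery for genes with fewer was not tested. Of unchanged genes, 86 of 9390, 46 of 10545 and 44 of 10357 were called apart. These had at least 50 UMIs over all 4 sets, where the rule counts the highest and lowest set. The alternatives were other cell filters (all barcodes, or at least 1000 UMIs and 500 genes with at most 10% mitochondrial UMIs), doublets kept, resolutions 0.5 and 2, each set left out in turn, CPM without mitochondrial and ribosomal protein genes, TMM scaling, the mean of per-cell CPM, cells thinned to 1000 UMIs, a ratio of 1.5, minimums of 50 or 1 UMIs for classes and 200 for sets, and marker members kept in the lists. Added after the data were seen were the classes without the doubtful clusters and each gene without its top cell in each set.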

Results

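The data were 1 pooled matrix of UMI counts (unique molecular identifiers, which count captured transcripts) from droplet sequencing of dissociated hippocampus of male adult Sprague Dawley rats. The series listed 4 titled samples, NC, MCAO, DEPR and MD, each with 1 library. MCAO is the blocking of the middle cerebral artery with a monofilament, a stroke model, and the descriptions of DEPR and MD both record chronic stress. The labels do not say what MD stands for. The design text describes 2 groups of 10 rats, both with MCAO and 1 of them then stressed, and hippocampi of 5 rats per group. The matrix held 32623 genes and 31638 barcodes with 180847756 UMIs. Its barcodes carried 4 suffixes, here called sets 1 to 4, with 7291, 8959, 5884 and 9504 barcodes and 43640627, 46669201, 36242408 and 54295520 UMIs. Median UMIs per barcode were 4631, 4383, 5679.5 and 5167.5. The labels and files used here tie no set to a titled sample, so each set's own value is given, no set is called a group, and the differences between NC, MCAO, DEPR and MD were not computed. With 1 library per titled sample, nothing here has a replicate check, and every interval covers counting error only.

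Microglia-like cells, the resident macrophages of the brain, made up 45.6% of the 27906 cells kept (exact 95% interval 45.0 to 46.2%). Oligodendrocyte-like cells, which form myelin, made up 28.3% (27.8 to 28.8%) and endothelial-like cells, which line the vessels, 11.2% (10.8 to 11.5%). These are the 3 cell types that the series title names. In sets 1 to 4 the microglia-like share was 46.3, 53.2, 37.1 and 43.0%, the oligodendrocyte-like share 19.9, 29.8, 36.6 and 28.1% and the endothelial-like share 15.8, 4.88, 12.5 and 12.8%. Endothelial-like cells were therefore least frequent in set 2, at 4.88% (exact 95% interval 4.42 to 5.37%), and most frequent in set 1, at 15.8% (14.9 to 16.7%). This share leaves out unnamed clusters 13 and 17, where 11 and 12 of 13 endothelial markers were enriched along with markers of other types. They held 302, 184, 40 and 84 cells and 40, 11, 43 and 84 cells in sets 1 to 4. Vessel wall cells followed at lower shares, with pericyte-like cells at 1.86, 0.602, 2.45 and 1.91% and smooth muscle-like cells at 1.37, 0.602, 2.10 and 1.70% in sets 1 to 4. Among immune cells, T cell-like cells were at 2.53, 2.32, 3.69 and 4.17%, monocyte-like cells at 0.821, 0.527, 0.965 and 1.38%, border macrophage-like cells at 0.647, 0.288, 0.618 and 1.75% and neutrophil-like cells at 0.363, 0.627, 0.193 and 0.416%. The cluster named ependymal-like was at 1.22, 0.991, 0.792 and 0.725%, and at resolution 2 it parted into 168 ependymal-like cells (64, 65, 24 and 15 in sets 1 to 4), 88 like oligodendrocyte precursors (13, 14, 16 and 45) and 2 others. The cluster named monocyte-like parted into 141 monocyte-like cells (20, 21, 28 and 72) and 119 like B cells (32, 21, 22 and 44), so the shares of these 2 clusters mix cell types. At resolution 1, no cluster was named for neurons, neuroblasts, astrocytes, oligodendrocyte precursors, committed precursors, fibroblasts, choroid plexus, dendritic cells, NK cells, B cells or red cells. The minimum was nevertheless met by 4 of 6 red cell markers in unnamed cluster 13, by 5 of 10 astrocyte markers in the ependymal-like cluster and by 3 of 7 NK cell markers in the T cell-like cluster, each of which matched another list better. No cluster met the list of dividing cells. At resolution 2, clusters of 88, 119 and 120 cells were named for precursors, B cells and red cells; all barcodes gave clusters for B cells and red cells, and the stricter filter for precursors and B cells. At resolution 1, another 4 clusters with 9.19, 6.23, 2.90 and 4.09% of the cells stayed unnamed. Enzymatic dissociation, lysis of red cells and the deposited minimum of 500 UMIs per barcode stand beside these shares, which are shares of cells recovered.

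**Figure D1:**
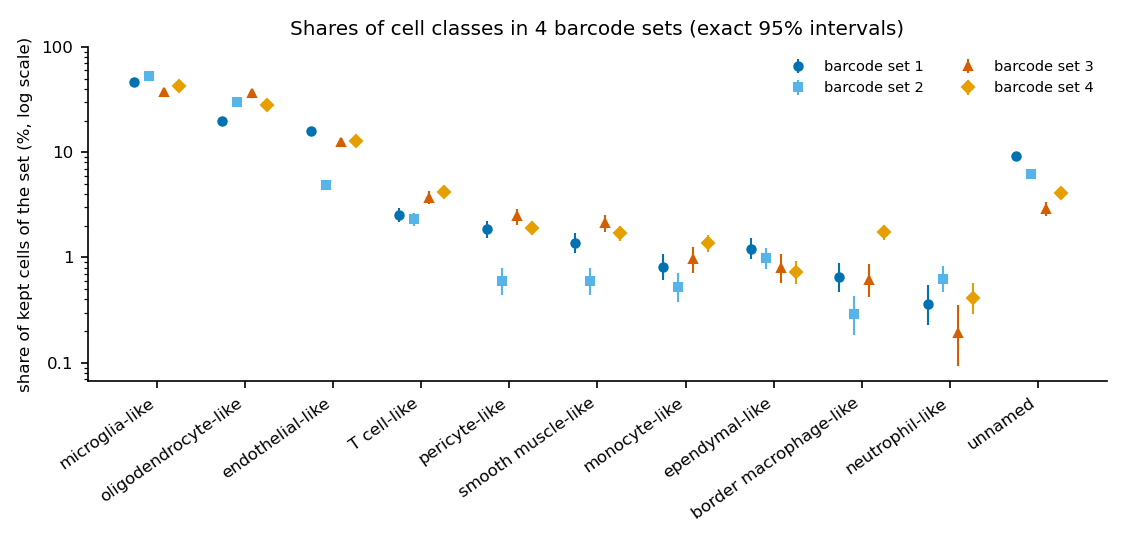
Share of the kept cells (percent, log axis) in each cell class, 1 point per barcode set 1 to 4, with exact binomial 95% intervals that cover counting error only. The ependymal-like and monocyte-like classes mix cell types. The microglia-like share lay between 37.1% and 53.2%, and the endothelial-like share between 4.88% and 15.8%.

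Endothelial-like cells stood apart by the machinery of the blood-brain barrier. Slco1c1, which carries thyroid hormone, had a median log2 ratio to the other named cells of 8.44 over the 4 sets (range 7.70 to 9.31; 964 against 3.25 CPM). The glucose transporter Slc2a1 was at 5.13 (5.10 to 5.45; 2230.2 against 56.5 CPM) and the drug efflux pump Abcb1a at 5.73 (5.51 to 5.94; 1530.2 against 28.6 CPM). The lymphatic VEGF receptor Flt4 (8.81) and Vwf, which binds platelets (7.94), were higher as well, while most cytokine, MHC class II and myelin genes were lower. The comparison asks which genes set each cell type of the title apart within a set. By UMIs the other named cells were mostly of the other focal classes (61651752 microglia-like, 48248927 oligodendrocyte-like and 17634316 endothelial-like). A gene high in a focal class therefore tends to come out low in the others. Of 12379 genes with enough UMIs, 1257 were at least 2-fold higher in every set and 1772 at least 2-fold lower. Outside the markers and the genes used for clustering the counts were 785 and 1390 of 10917. Of the 29 gene lists, 8 had medians above and 8 below nearly all matched random lists (outside the middle 95% of them in every set). Values beside genes and lists are median log2 ratios over the sets.

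Lists of vessel function lay above the random lists. Barrier transporters had 11 of 12 higher and 0 lower, median 5.10, with Slc3a2, a subunit of amino acid carriers, at 2.54. Barrier junction genes had 6 of 7 higher and 0 lower, median 3.19, from cingulin (Cgn, 5.51) to F11r, a junctional adhesion molecule (2.14). Angiogenesis and VEGF signalling had 6 of 10 higher and 0 lower, median 3.33. Its members included Nrp1, a VEGF co-receptor (3.67), and Angpt2, which loosens vessels and ranged from 1.22 to 7.56 over the sets. Apln, a ligand released by growing vessels, was at -0.42 and did not pass. Leukocyte adhesion had 3 of 5 higher and 1 lower, median 2.72, with Icam2 at 6.06 and Icam1, which binds activated leukocytes, lower at -1.58. The venous list had 3 of 6 higher and 1 lower, median 4.74; the amino acid carrier Slc38a5 was at least 8.71, since 1 set had no UMI in the other cells. The arterial list (3 of 7 higher and 0 lower, median 0.86) stayed within the random lists but lay above with at least 1 UMI (3.24), with Sema3g, a guidance cue, at 4.34 and the calcification inhibitor Mgp at 0.33. Its list median was 3.55 in set 2, against 0.61, 0.68 and 1.05 in sets 1, 3 and 4. Interferon response genes had 9 of 13 higher and 0 lower, median 2.28, from Ifit1, which binds viral RNA (4.44), to Bst2, which tethers virus particles (1.76). The disease-associated oligodendrocyte list was above too (5 of 11 higher and 4 lower, median 1.22), through members such as complement C4b (3.35), against lower values of the protease Klk6 (-4.72). Cell death genes had 3 of 11 higher and 0 lower, median 0.95, with the p53 target Pmaip1 at 3.86 and the kinase Ripk1 at 1.37; this list no longer lay above without set 3 (0.88), under the stricter filter (0.77), with doublets kept (0.90) or with at least 50 UMIs (0.74).

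Immune and myelin lists lay below. The list of pro-inflammatory cytokines and NF-kB genes, here called the cytokine list, had 1 of 14 higher and 9 lower, median -3.95. The neutrophil attractant Cxcl2 was at -5.30 and the prostaglandin synthase Ptgs2 higher at 5.31. MHC class II had 0 of 6 higher and 4 lower, median -4.61, from RT1-Bb (-4.52) to RT1-Db1 (-4.87). Complement had 2 of 7 higher and 4 lower, median -3.05, with the inhibitor Cd59 higher at 3.86 and C3, the central component, at -4.49. Homeostatic microglia genes had 0 of 5 higher and 4 lower, median -4.07, with the microglial transcription factor Sall1 at -4.13, and disease-associated microglia genes 1 of 17 higher and 10 lower, median -1.82, with lipoprotein lipase (Lpl) at 3.78 and Gpnmb at -4.78. Phagocytosis and lysosome genes had 1 of 9 higher and 6 lower, median -2.51, from Gas6, a bridge to dying cells (3.24), to cathepsin S (Ctss, -4.75). Myelin had 0 of 4 higher and 4 lower, median -4.92, with the tight junction protein Cldn11 at -4.95, and support of axons 0 of 6 higher and 4 lower, median -3.18, with Ptgds, a prostaglandin D synthase, at -5.22.

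The remaining lists stayed within the random lists. Glucocorticoid response had 4 of 15 higher and 3 lower, median -0.03, from the sulfotransferase Sult1a1 (4.21) to Fkbp5, which dampens the glucocorticoid receptor (-3.07). The hormone receptors had 0 of 3 higher and 0 lower, median 0.53, with the mineralocorticoid receptor Nr3c2 at 1.62. Immediate early genes had 1 of 14 higher and 1 lower, median 0.54, with the stress factor Atf3 at 1.79 and Egr2 at -2.05; the list lay above without set 1 or set 2 (0.80 each), at resolution 2 (0.55), with thinned cells (0.42), with at least 50 UMIs (0.54) and without the doubtful clusters (0.52). Heat shock had 0 of 7 higher and 3 lower, median -0.999, with the mitochondrial chaperones Hspd1 (-1.29) and Hspe1 (-1.93). For MHC class I the counts were 2 of 8 higher and 0 lower, median 0.55, with the peptide transporter Tap2 at 1.33 and B2m at 1.30. Hypoxia response had 4 of 13 higher and 2 lower, median 0.30, with hexokinase Hk2 lower at -4.49. Cholesterol synthesis had 0 of 15 higher and 1 lower, median -0.27, with its brake Insig1 at -1.18. ER stress had 1 of 10 higher and 1 lower, median -0.24, with the kinase inhibitor Trib3 at 2.86. Oxidative stress had 2 of 10 higher and 0 lower, median 0.46, with the quinone reductase Nqo1 at 3.31 and superoxide dismutase Sod1 at 1.38; without set 1 this list lay above, at 0.46. Growth factors and receptors had 3 of 14 higher and 6 lower, median -1.03, from Igf1r, the IGF receptor (3.74), to Fgfr2 (-3.75). Monoamine and neurotransmitter signalling had 3 of 9 higher and 2 lower, median -0.45, from Maob, which breaks down dopamine (5.53), to the adenosine receptor Adora1 (-4.58). Cell cycle genes had 0 of 4 higher and 0 lower, median -0.23, with the replication clamp Pcna at 0.11. Other members named by the fixed rule were the lower calls Selplg (-4.61), Tspan2 (-2.79) and Cntf (-2.51), and Idi1 (0.40) and Cdc20 (-0.90), which did not pass. The gap junction gene Gja5 was at least 6.56 and Asns of the ER stress list at most -1.63, each with 2 counts of 0. TMM scaling ended the calls on F11r and Bcl2l1. Among the genes given a value here, the stricter cell filter ended the calls on Asns, C4b, Cgn, F11r, Gja5, Insig1 and Ripk1, and the mean of per-cell CPM those on Asns, F11r, Hspd1, Insig1 and Ripk1. Among the same genes, a minimum of 50 UMIs ended the calls on C4b, Cgn, Flt4 and Gja5, and leaving out the doubtful clusters those on Asns, Cgn and Gja5. The call on Cgn also ended with all barcodes, with doublets kept and at resolution 2. Thinning ended, among the same genes, the calls on Adora1, Asns, C4b, Cgn, Cntf, F11r, Flt4, Gja5, Hspd1, Ifit1, Insig1, Ripk1, Selplg, Sema3g, Tap2 and Trib3. Cells thinned to 1000 UMIs ended the calls on complement (-2.12), leukocyte adhesion (2.35), venous (1.56) and cell death genes (0.60), and the mean of per-cell CPM those on complement (-2.69) and cell death genes (0.45).

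Microglia-like cells stood apart by immune signalling and surveillance genes. These are levels after enzymatic dissociation, and levels in the intact tissue were not measured. What dissociation adds to cytokine, immediate early, heat shock or ER stress genes was not tested. Cathepsin S (Ctss), a lysosomal protease, was at 6.32, the cytokine Il1a at 6.26 and the fructose transporter Slc2a5 at 6.06. The chemokines Ccl3 (5.46) and Ccl4 (5.04), which attract leukocytes, were higher too, while the myelin list and most vessel lists lay below the random lists. Of 12379 genes, 1107 were higher and 3973 lower in every set, so that 21.8% of the calls were higher. TMM scaling gave 1848 higher and 2715 lower (40.5% higher) and moved the median of all genes by 0.64, from -0.70 to -0.06. Log2 values in the microglia-like part are therefore given relative to that median of -0.70. The higher and lower calls and the random lists rest on the ratios before it is taken off. Outside markers and clustering genes 915 were higher and 3099 lower of 10917. Of the 29 lists, 8 lay above and 8 below the random lists.

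The lists above were these. Homeostatic microglia genes had 4 of 5 higher and 0 lower, median 5.04, from Slc2a5 down to Sall1 (3.79), with Selplg, a ligand of selectins, at 6.03. Pro-inflammatory cytokines and NF-kB genes had 12 of 14 higher and 1 lower, median 3.98, the lower member being Ptgs2 (-1.90). MHC class II had 5 of 6 higher and 0 lower, median 4.64, from RT1-Ba (4.82) to RT1-Bb (4.49). Complement had 4 of 7 higher and 2 lower, median 2.60, with the receptor C3ar1 at 5.83 and C3 at 5.38, against Cd59 at -4.995. Heat shock had 5 of 7 higher and 0 lower, median 2.66, with the co-chaperone Dnajb1 at 3.29 and the inducible chaperone Hspa1b at 3.17. Phagocytosis and lysosome genes had 4 of 9 higher and 0 lower, median 2.57, down to Mertk, a receptor for dying cells (4.15). Immediate early genes had 7 of 14 higher and 0 lower, median 2.03, with Egr2 at 3.75 and Jun at 2.14. ER stress had 3 of 10 higher and 1 lower, median 1.75, with Herpud1, which clears misfolded protein, at 3.13 and the chaperone Hspa5 at 2.10.

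The lists below held vessel, myelin and lipid genes. Myelin had 0 of 4 higher and 4 lower, median -5.28, with the myelin gene regulator Myrf at -4.05, and support of axons 0 of 6 higher and 6 lower, median -4.71, with carbonic anhydrase Car2 at -4.59. The venous list had 1 of 6 higher and 4 lower, median -4.78, with the venous regulator Nr2f2 at -5.58 and Icam1 higher at 4.08. The arterial list had 1 of 7 higher and 5 lower, median -4.61, with the guidance ligand Efnb2 higher at 3.54 and Vegfc at -5.93. Angiogenesis had 1 of 10 higher and 6 lower, median -3.83, with Plvap, a protein of vessel pores, higher at 6.30 and Flt4 at -6.02. Barrier transporters had 0 of 12 higher and 10 lower, median -3.14, with the organic anion carrier Slco1a4 at -5.73. Cholesterol synthesis had 0 of 15 higher and 10 lower, median -1.36, with its brake Insig1 at -1.08. Monoamine and neurotransmitter signalling had 0 of 9 higher and 6 lower, median -2.72, with Maob at -5.87 and the GABA receptor Gabbr1 at -2.72.

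Within the random lists lay glucocorticoid response (1 of 15 higher and 6 lower, median 0.00), with the phosphatase Dusp1 at 2.51 and the transcription factor Zbtb16 at -6.55, and the hormone receptors (0 of 3 higher and 1 lower, median -0.26), with Hsd11b1, which regenerates corticosterone, at -2.90. Disease-associated microglia genes were within as well (6 of 17 higher and 3 lower, median 2.11), with osteopontin (Spp1) at 5.87, Apoe, which carries lipid, at 3.40 and Lpl at -5.61; the list lay above without set 4 (1.63), with all barcodes (1.89), under the stricter filter (1.07), with doublets kept (1.33) and with marker members kept (1.56), each before the median of all genes is taken off, so this call rests on the setting. Interferon response had 1 of 13 higher and 3 lower, median -0.23, with the antiviral GTPase Mx1 at 2.13 and Ifit1 at -2.74. For MHC class I the counts were 2 of 8 higher and 0 lower, median 1.22, with RT1-CE10 at 2.72. Barrier junctions had 0 of 7 higher and 4 lower, median -2.06, with the scaffold Tjp1 at -4.56, and leukocyte adhesion 1 of 5 higher and 2 lower, median 0.27, with Icam1 at 4.08 and Vwf at -5.26. Hypoxia response had 1 of 13 higher and 5 lower, median -0.02, with Hk2 at 3.84 and Ndrg1 at -4.12. Oxidative stress had 3 of 10 higher and 5 lower, median -0.08, with haem oxygenase Hmox1 at 3.71 and Nqo1 at -3.03. The disease-associated oligodendrocyte list had 1 of 11 higher and 3 lower, median 0.62, with the alarmin Il33 at 5.87 and apolipoprotein D (Apod) at -5.60. Cell death had 2 of 11 higher and 2 lower, median 0.86, with Ripk3, a kinase of necroptosis, at 2.68 and the survival gene Bcl2l1 at -1.32. Growth factors had 2 of 14 higher and 5 lower, median 0.43, with the TGF-beta receptor Tgfbr1 at 4.08 and Fgfr2 at -5.31. Cell cycle had 0 of 4 higher and 1 lower, median 0.27, with Cdc20, which drives mitotic exit, at -1.06. Other members named by the fixed rule were the higher calls Klf2 (1.93), Hspa8 (2.10) and RT1-A2 (2.55), the lower calls Cgn (-2.16), Tspan2 (-5.37), Ptgds (-5.76) and Adora1 (-1.99), and Pcna (0.93), which did not pass. TMM scaling ended 11 of the 156 calls on list genes, all of them lower calls: Asns, Cat, Fas, Ifit1, Ifit3, Mt1, Pdgfa, Pfkfb3, Ptgs2, Slc16a1 and Sod1. Cells thinned to 1000 UMIs ended the calls on heat shock and ER stress genes (1.89 and 1.16 before the median of all genes is taken off), and the stricter cell filter that on heat shock (1.97 on the same scale, as without this filter). The list of barrier junctions lay below with marker members kept (-4.11 before the median of all genes is taken off). Among the genes given a value here, the stricter filter ended the calls on Mx1 and Cgn, the mean of per-cell CPM those on Klf2 and Mx1, a minimum of 50 UMIs those on Cgn, Flt4 and Plvap, and thinning those on Cdc20, Cgn, Flt4, Hsd11b1, Ifit1, Mx1, Plvap and Vegfc. The call on Cgn also ended with all barcodes, with doublets kept, at resolution 2 and without the doubtful clusters.

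Oligodendrocyte-like cells stood apart by myelin and lipid genes. Their immune and vascular lists lay low against the other named cells, which by UMIs were mostly microglia-like and endothelial-like and so carry these genes. The myelin junction gene Cldn11 was at 6.54 (range 6.32 to 6.98; 2003 against 21.3 CPM). Ptgds, a prostaglandin D synthase, was at 6.64 (5.30 to 7.13), and the protease Klk6 at 6.84. Of 12379 genes, 2114 were higher and 3238 lower in every set; outside markers and clustering genes the counts were 2063 and 2090 of 10917. Of the 29 lists, 3 lay above and 18 below the random lists.

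The lists above were myelin (4 of 4 higher and 0 lower, median 6.10), down to the tetraspanin Tspan2 (5.26), support of axons (4 of 6 higher and 0 lower, median 5.86), down to Car2 (5.71), and cholesterol synthesis (9 of 15 higher and 0 lower, median 1.69), with the desaturase Sc5d at 2.97. The immune lists lay below. Pro-inflammatory cytokines and NF-kB genes had 0 of 14 higher and 14 lower, median -5.61, from the NF-kB subunit Relb (-2.89) to Ptgs2 (-6.86). Interferon response had 0 of 13 higher and 12 lower, median -4.63, from Ifi27 (-2.34) to Ifit3 (-6.86). MHC class II had 0 of 6 higher and 6 lower, median -5.48, with RT1-Bb at -6.14. For MHC class I the counts were 0 of 8 higher and 8 lower, median -3.88, with the peptide loader Tapbp at -2.47 and RT1-CE10 at -4.57. Complement had 0 of 7 higher and 6 lower, median -4.99. Homeostatic microglia genes had 0 of 5 higher and 4 lower, median -5.03, with Sall1 at -2.25 and Selplg at -5.62. Disease-associated microglia genes had 1 of 17 higher and 14 lower, median -3.95, with the tetraspanin Cd9 higher at 2.68 and Lpl at -6.11. Phagocytosis genes had 0 of 9 higher and 6 lower, median -4.999, with the lysosomal protein Cd68 at -4.98. Vascular lists lay below too. Barrier junctions had 1 of 7 higher and 5 lower, median -3.80, with occludin (Ocln) at -5.77. Barrier transporters had 0 of 12 higher and 8 lower, median -4.77, with Slc2a1 at -2.56 and Slc22a8 at -6.82. Leukocyte adhesion had 0 of 5 higher and 5 lower, median -6.34, with Icam1 at -5.54. Angiogenesis had 1 of 10 higher and 9 lower, median -4.99, with Apln higher at 4.21 and Angpt2 at -6.20. The arterial list had 1 of 7 higher and 6 lower, median -4.82, with the guidance receptor Unc5b higher at 3.37, and the venous list 0 of 6 higher and 6 lower, median -5.58, with Vwf at -6.51. Immediate early genes had 0 of 14 higher and 14 lower, median -3.17, from Fos (-2.22) to the endothelial regulator Klf2 (-5.76). Cell death had 0 of 11 higher and 9 lower, median -4.14, from Ripk1 (-1.88) to Pmaip1 (-6.16). Growth factors had 2 of 14 higher and 8 lower, median -2.11, with Fgfr2 higher at 5.34 and Tgfb1 at -5.62. The disease-associated oligodendrocyte list lay below although Klk6 and Apod (6.36) were higher (2 of 11 higher and 7 lower, median -3.26), with Socs3, which damps cytokine signals, at -5.30.

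Within the random lists lay glucocorticoid response (1 of 15 higher and 4 lower, median -0.73), with Pdk4, which spares glucose, at 2.996 and the metallothionein Mt2A at -4.91, and the hormone receptors (0 of 3 higher and 1 lower, median -1.47). Heat shock had 0 of 7 higher and 4 lower, median -2.94, with Hspb1 at -5.37 and Dnajb1 at -3.03; without set 1 the list lay below, at -3.21. Hypoxia response had 2 of 13 higher and 5 lower, median -0.40, with Bnip3, which triggers removal of mitochondria, at 3.23 and adrenomedullin (Adm) at -6.02. ER stress had 0 of 10 higher and 6 lower, median -1.33, with Ddit3 at -1.14. Oxidative stress had 1 of 10 higher and 4 lower, median -0.63, with the peroxidase Prdx1 at 2.27 and Hmox1 at -4.71. Monoamine and neurotransmitter signalling had 2 of 9 higher and 2 lower, median -0.34, with Adora1 at 3.77 and Maob at -5.47. Cell cycle had 0 of 4 higher and 0 lower, median -0.34, with the replication gene Mcm2 at -0.40. Other members named by the fixed rule were the lower calls Serping1 (-5.65), Ctss (-5.49) and Vegfc (-5.77), and Hsd11b1 (-1.47) and Pcna (-0.29), which did not pass. Values that are bounds, because a count was 0 in at least 1 set, were Ciita at most -3.83, C4b at most -2.52, Gja5 at most -2.38, Ephb4 at most -4.85 and Trib3 at most -3.94. TMM scaling kept all 192 calls on list genes. The stricter cell filter ended the call on growth factors (-1.20), thinning to 1000 UMIs those on growth factors (-1.88) and homeostatic genes (-4.72), and the mean of per-cell CPM that on barrier junctions (-3.43). Among the genes given a value here, the stricter filter ended the calls on C4b, Ddit3 and Gja5, all barcodes that on Ddit3, a minimum of 50 UMIs those on C4b, Ciita and Gja5, leaving out the doubtful clusters that on Gja5, and thinning those on C4b, Ciita, Ephb4, Gja5, Pdk4, Relb, Trib3 and Vegfc.

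**Figure D2:**
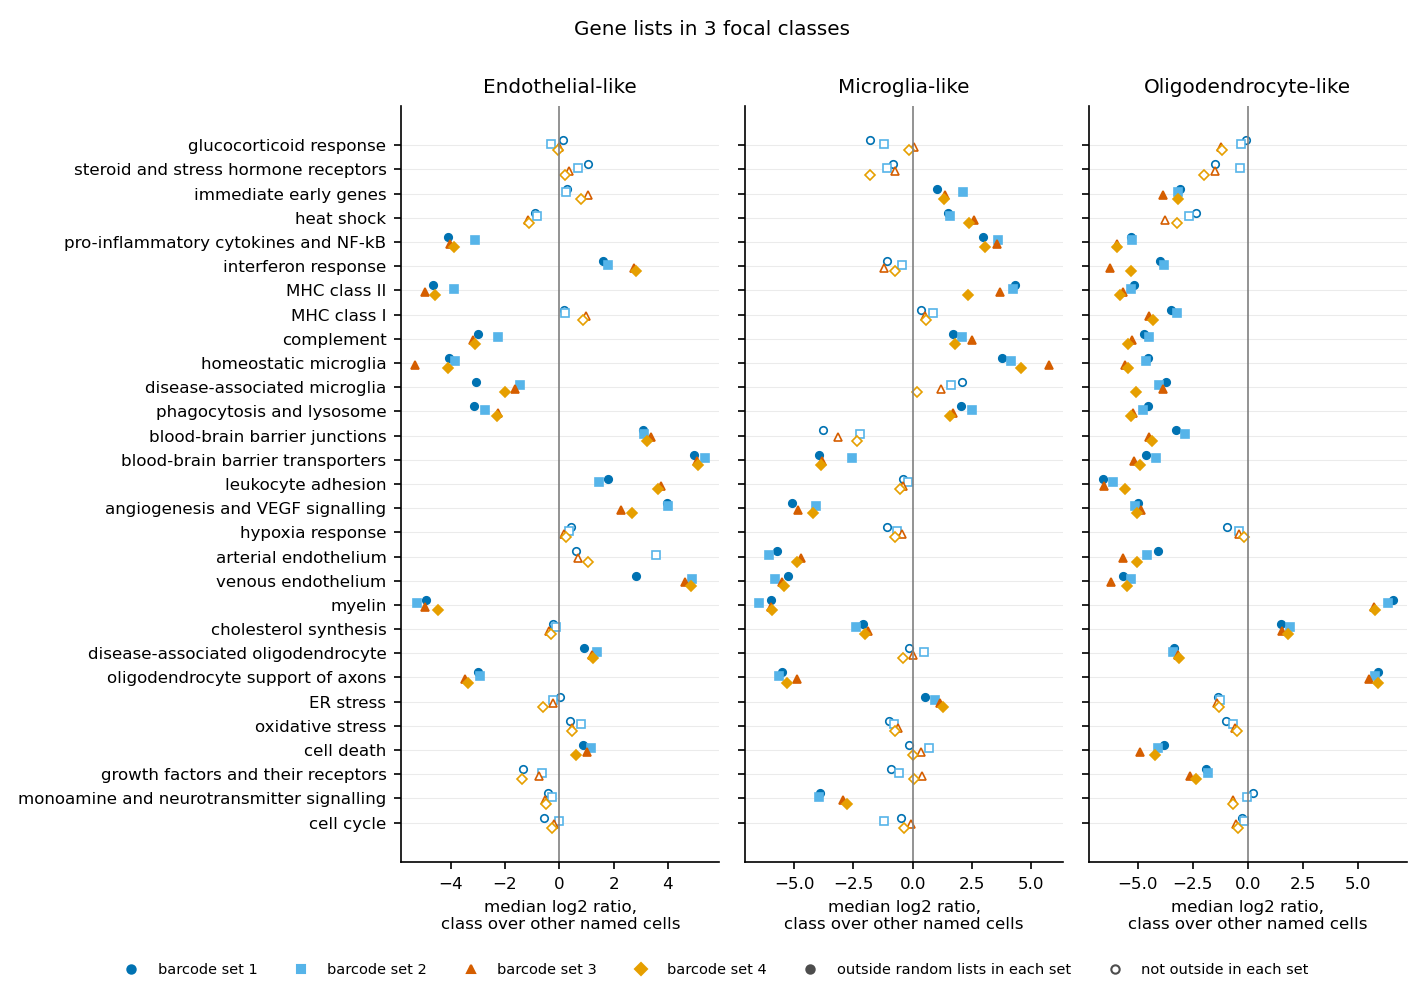
Median log2 ratio of each of the 29 gene lists in endothelial-like, microglia-like and oligodendrocyte-like cells against all other named cells, 1 marker per barcode set, filled where the list lay outside the random lists in each set. Barrier transporters lay at 5.10 in endothelial-like cells and myelin genes at 6.10 in oligodendrocyte-like cells. The microglia-like panel shows ratios before the median of all genes is taken off, unlike the text.

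Within endothelial-like cells, genes of vessel remodelling and hypoxia and a chemokine lay apart between the sets. Angpt2, which destabilises vessels, was at 688, 449.8, 17.2 and 15.7 CPM in sets 1 to 4 (highest over lowest 44.0-fold, 95% interval 35.3 to 55.4). The hypoxia gene Ndrg1 was at 1483, 1344, 272 and 294 CPM (6.24-fold) and adrenomedullin (Adm), which widens vessels, at 353, 264, 62.1 and 75.2 CPM (6.50-fold). Cxcl9, an interferon-induced T cell attractant, was at 5.51, 2.48, 93.9 and 128 CPM (51.7-fold, 95% interval 22.1 to 159.9). The question is how far the 4 unassigned libraries differ within a cell type. A gene lay apart when the CPM of the highest and lowest set differed at least 2-fold with an interval that left out 1. Of 8219 genes measured, 1193 (14.5%) lay apart, 184 at least 4-fold and 62 at least 8-fold. The highest value was in sets 1 to 4 for 17.2%, 14.5%, 23.6% and 44.7% of them. With TMM scaling 1006 lay apart, with 34.8%, 19.2%, 20.3% and 25.7%, and 852 of the 1193 were kept. TMM moved the median log2 ratio of all genes by 0.20 between sets 1 and 3, 0.25 between sets 1 and 4, 0.12 between sets 2 and 3 and 0.17 between sets 2 and 4. Folds without an interval in the endothelial-like and microglia-like parts are therefore on TMM totals. Different clusters held the class: cluster 4 held 920, 314, 1 and 9 of its 1000, 389, 650 and 1074 cells in sets 1 to 4, and cluster 7 held 55, 34, 647 and 1007.

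Of the list genes 98 lay apart, 62 of them by more than free RNA of the other named classes can bring at the level measured here, and 85 under TMM. Hypoxia response had 8 of 12 apart (6 above free RNA), including lactate dehydrogenase (Ldha, 562, 503, 224 and 239 CPM). The glycolytic activator Pfkfb3 was highest in set 4 (15.6, 7.93, 37.4 and 39.0 CPM). Angiogenesis had 7 of 13, among them Apln at 85.7, 44.6, 14.04 and 13.4 CPM and its receptor Aplnr at 2.76, 7.43, 26.0 and 23.3 CPM. Glucocorticoid response had 6 of 13 apart, with the cell cycle inhibitor Cdkn1a at 469, 514, 159 and 181 CPM (3.49-fold), Sult1a1 at 288, 312, 122 and 104 CPM (3.38-fold) and the salt-sensing kinase Sgk1 at 359.99, 369, 175 and 184 CPM. Interferon response had 6 of 13, with Mx1 at 29.5, 17.3, 3.64 and 4.97 CPM and Irf7, which drives type I interferon, at 120.1, 83.7, 36.9 and 33.0 CPM; Ifit1, highest in set 4, was no longer apart under TMM. Heat shock had 5 of 7, of which TMM kept Hsph1 (87.5, 89.7, 202 and 279 CPM) and Dnajb1 (257, 357, 473 and 627 CPM). Barrier transporters had 5 of 12, with the transferrin receptor Tfrc at 214, 209, 609 and 578 CPM and the lactate carrier Slc16a1 at 68.6, 71.8, 36.1 and 25.4 CPM. Leukocyte adhesion had 4 of 6, with Vcam1 at 69.5, 130.3, 119 and 223 CPM and Vwf at 1267, 1335, 623 and 633 CPM, and the arterial list 4 of 7, with Mgp at 75.8, 924, 200.5 and 199 CPM (11.5-fold). Immediate early genes had 0 of 14 apart. Myelin (9 of 12), cytokine (7 of 10), MHC class II (4 of 4) and complement genes (6 of 8) lay apart mostly within the free RNA level, whose median was highest in set 2 at 3.61%. Among the 10 genes of largest ratio, the retinal transporter gene Abca4 (148, 104, 0.520 and 1.72 CPM, 284-fold, 95% interval 78.3 to 2346), the sulfotransferase Chst1 (136-fold, 95% interval 24.2 to 5394), Kcnmb4, a potassium channel subunit (46.5-fold, 95% interval 15.6 to 228), and the adhesion receptor Adgrg6 (44.2-fold, 95% interval 23.0 to 97.6) stayed apart without each gene's top cell in each set. Haemoglobin Hbb was at 512, 403, 27.3 and 8.79 CPM. The neutrophil genes S100a8 (4.74, 279, 0.520 and 2.10 CPM, 536-fold, 95% interval 148 to 4439) and S100a9 (26.6, 538, 3.64 and 4.01 CPM) and placental growth factor (Pgf, 56.9-fold, 95% interval 9.89 to 2279) did not. Without the doubtful cluster 5, which has few UMIs per cell, 1064 of the 1193 genes were kept. Other list members apart were, above the free RNA level, Abcg2, Ankrd37, Bcl2l1, Bnip3, C4b, Cd34, Cd9, Ctsl, Errfi1, Fgfr1, Fth1, Gja4, Gja5, Gria2, Hmox1, Hspa1b, Hspb1, Hspe1, Ifit3, Il33, Isg15, Lpl, Maob, Marveld2, Mbp, Nfkbia, Nr2f2, P2rx4, Pdgfb, Sall1, Sele, Sema3g, Slc38a5, Slc7a5, Slco1c1, Tek, Tgfb2, Trib3, Usp18 and Zbtb16, and within it C1qa, C1qb, C1qc, C3, Ccl2, Ccl3, Ccl4, Cd74, Cldn11, Csf1r, Ctss, Cx3cr1, Cxcl1, Cxcl2, Ermn, Fgfr2, Hapln2, Hk2, Il1b, Lgals3, Lyz2, Mag, Mobp, Mog, Nlrp3, Opalin, RT1-Ba, RT1-Da, RT1-Db1, Serping1, Tmem119, Trem2, Tyrobp and Vegfa. Of these, TMM scaling ended the calls on Abcg2, Cldn11, Cx3cr1, Fgfr1, Fgfr2, Hspa1b, Hspb1, Hspe1, Mag, Maob, Mobp and Tek.

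Microglia-like cells of the 4 sets lay apart in interferon, heat shock and homeostatic genes. Some interferon and heat shock genes differed outside this class too. In T cell-like cells Isg15 was at 309, 192, 66.6 and 65.3 CPM and Hspa1b at 178, 337, 753 and 596 CPM. The other way ran Isg15 in border macrophage-like cells (11.3, 46.9, 81.4 and 38.3 CPM) and Hspb1 in ependymal-like cells (512, 563, 389 and 365 CPM). What dissociation adds to heat shock genes was not tested. Of the interferon response list 11 of 12 lay apart (9 above free RNA), led by Irf7 at 18.3, 7.79, 1.37 and 1.15 CPM (17.9-fold) and Mx1 at 76.8, 41.5, 15.2 and 17.5 CPM (5.62-fold). Heat shock had 6 of 7 apart, with Hspb1 at 934, 1363, 4371 and 4573 CPM (4.36-fold) and Dnajb1 at 544, 703, 2255 and 2468 CPM (4.04-fold). Homeostatic genes had 6 of 11, with Gpr34, a receptor for lysophosphatidylserine, at 63.8, 62.4, 228 and 244 CPM (3.43-fold) and the fractalkine receptor Cx3cr1 at 147, 178, 359 and 411 CPM. Of 9761 genes, 1449 (14.8%) lay apart, 344 at least 4-fold and 139 at least 8-fold, with the highest value in sets 1 to 4 for 20.2%, 14.8%, 25.7% and 39.3%. With TMM scaling 1363 lay apart, with 26.4%, 22.7%, 22.2% and 28.7%, and 1207 of the 1449 were kept. TMM moved the median of all genes by 0.15 between sets 1 and 3, 0.17 between sets 1 and 4 and between sets 2 and 3, and 0.19 between sets 2 and 4. Clusters 0, 9 and 2 held 1574, 596 and 8 of the 2934 cells in set 1, 2429, 1166 and 61 of 4240 in set 2, 22, 4 and 1594 of 1924 in set 3, and 58, 16 and 2966 of 3623 in set 4.

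Of the list genes 109 lay apart, 72 above free RNA and 98 under TMM. Disease-associated microglia genes had 7 of 16 apart, with the phagocytic receptor Axl at 89.8, 68.1, 8.66 and 9.72 CPM (11.5-fold), the fungal receptor Clec7a at 71.7, 58.6, 9.09 and 13.8 CPM, galectin 3 (Lgals3) at 62.4, 55.9, 8.06 and 8.15 CPM and Cd9 at 95.7, 95.1, 296 and 279.7 CPM. Glucocorticoid response had 5 of 12 (3 above free RNA), with Fkbp5 at 112, 126, 16.7 and 19.5 CPM (8.48-fold) and Tsc22d3, a mediator of glucocorticoid action, at 537, 685, 317 and 360.4 CPM. MHC class II had 4 of 7, with RT1-Ba at 3880.2, 3526, 1260.2 and 1099.5 CPM, and MHC class I 3 of 8, with RT1-CE10 at 6672, 5985, 2349.7 and 2350.4 CPM. Phagocytosis genes had 6 of 11, with Cd68 at 275, 283, 100.2 and 86.4 CPM, and oxidative stress 2 of 9, with Hmox1 at 119, 117, 417 and 439 CPM (3.28-fold). Growth factors had 5 of 9, with Tgfbr1 at 116, 113, 278 and 282 CPM. Complement had 5 of 10 apart and cytokines 5 of 14, with Il1a at 66.3, 65.9, 159 and 167 CPM and Il6 at 37.7, 44.3, 13.9 and 13.6 CPM. The junction gene F11r was at 9.71, 12.8, 115 and 105 CPM (10.6-fold). All 9 myelin genes apart, of 13, lay within the free RNA level. The 10 genes of largest ratio included Cxcl13, which attracts B cells (149.6, 91.7, 3.69 and 1.88 CPM, 79.5-fold, 95% interval 57.2 to 114), the ubiquitin-like modifier Ubd (144, 128, 1.80 and 1.67 CPM, 86.3-fold, 95% interval 60.9 to 127), the secreted protease Htra3 (0.0783, 0.663, 16.9 and 16.8 CPM, 216-fold, 95% interval 38.3 to 8562) and the retinol dehydrogenase Dhrs9 (0.313, 0.166, 17.6 and 24.6 CPM, 149-fold, 95% interval 50.5 to 723). The others were Tmem171 (135-fold, 95% interval 23.6 to 5393), neurofilament Nefh (115-fold, 95% interval 20.3 to 4595), Mctp1 (83.4-fold, 95% interval 14.7 to 3321), Ccdc152 (76.0-fold, 95% interval 13.4 to 3028), Mctp2 (75.5-fold, 95% interval 13.1 to 3027) and Ppfia4 (74.7-fold, 95% interval 13.03 to 2988), each under 10 CPM in every set. Without the low-UMI clusters 1 and 6, 1318 of the 1449 genes were kept. Other list members apart were, above the free RNA level, Adm, Adora1, Bcl2, Bst2, C1qa, C1qc, C4a, Chac1, Ciita, Dusp1, Efnb2, Fdft1, Fgfr1, Gabbr1, Gas6, Gpnmb, Hspa1b, Hspd1, Hspe1, Hsph1, Ifi27, Ifit2, Irgm, Itgax, Itgb5, Lyz2, Mlkl, Msmo1, Msr1, Nlrp3, Oasl, P2rx4, P2ry13, Plvap, Psmb8, RT1-DMb, RT1-Da, Rsad2, Selplg, Sema3g, Siglec5, Slc16a1, Socs3, Sod2, Srebf2, Tapbp, Tgfbr2, Usp18, Vcam1 and Vegfa, and within it Abcg2, Apod, Car2, Cdh5, Cldn5, Cnp, Cntf, Cxcl1, Ermn, Esam, Fgfr2, Flt1, Ifit3, Igf1, Isg15, Klk6, Mag, Mbp, Mgp, Mki67, Mog, Mt1, Mt2A, Myrf, Ndrg1, Opalin, Ptgs2, Serping1, Slco1a4, Slco1c1, Tek, Tjp1, Unc5b and Vwf. Of these, TMM scaling ended the calls on Chac1, Fdft1, Gas6, Lyz2, Mag, Mgp, Mog, Ndrg1, Selplg, Tgfbr2 and Tjp1.

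Oligodendrocyte-like cells of the 4 sets lay apart in glucocorticoid response genes, 10 of 15 of the list (8 above free RNA). The members not apart were Tsc22d3 (164, 179, 144 and 160 CPM), Klf9 (194, 206, 144 and 159 CPM), Per1, Mt1 and Mt2A. The median log2 ratio of highest over lowest set was 1.72 for this list. It was larger for interferon response (2.97), MHC class I (1.85) and MHC class II (1.75). Sult1a1 was at 162, 179, 0.790 and 0.456 CPM in sets 1 to 4 (393-fold, 95% interval 190.5 to 979), Pdk4 at 53.6, 49.7, 4.98 and 4.56 CPM (11.7-fold, 95% interval 9.09 to 15.4), Zbtb16 at 63.4, 55.4, 8.38 and 8.28 CPM (7.66-fold, 95% interval 6.29 to 9.39), Fkbp5 at 82.1, 80.2, 14.4 and 12.98 CPM (6.33-fold, 95% interval 5.38 to 7.46) and Sgk1 at 2019, 2038, 368 and 364 CPM (5.61-fold, 95% interval 5.45 to 5.77). The bone morphogenetic protein Bmp4, which steers differentiation, was at 68.0 and 69.9 CPM in sets 1 and 2 and had 0 and 2 UMIs in sets 3 and 4 (at least 295-fold). Of 9503 genes, 864 (9.09%) lay apart, 171 at least 4-fold and 60 at least 8-fold, with the highest value in sets 1 to 4 for 21.2%, 31.7%, 20.02% and 27.1%. TMM scaling kept 785 of them and gave 835 in all. Clusters 3, 22 and 20 held 1191, 13 and 16 of the 1260 cells in set 1, 2207, 43 and 37 of 2372 in set 2, 19, 1589 and 267 of 1896 in set 3, and 39, 1931 and 354 of 2364 in set 4.

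Of the list genes 77 lay apart, 38 above free RNA and 73 under TMM. Interferon response had 6 of 6 apart (3 above free RNA), with Ifi27 at 265, 232, 39.6 and 42.5 CPM and the interferon brake Usp18 at 8.26, 6.35, 0.474 and 0.522 CPM. MHC class I had 4 of 6, with RT1-CE10 at 286, 328, 62.0 and 62.5 CPM and B2m at 733, 801, 326 and 356 CPM. Heat shock had 4 of 7, with Hspa1b at 128, 132, 306 and 619 CPM and Dnajb1 at 67.7, 84.6, 94.2 and 198 CPM. Immediate early genes had 8 of 13, with Egr1 at 432, 479.6, 324 and 699.8 CPM. The disease-associated oligodendrocyte list had 6 of 8, with Klk6 at 228, 261, 447 and 481 CPM and Cdkn1a at 148, 156, 39.4 and 45.3 CPM. Support of axons had 3 of 7, with Car2 at 1869, 1998, 4589.8 and 4859.7 CPM and Ptgds at 23140.1, 26058, 11714 and 11756 CPM. Hypoxia response had 3 of 12, with Hk2 at 87.0, 65.2, 41.5 and 29.0 CPM, and barrier transporters 4 of 8, with the lipid carrier Mfsd2a at 107, 102, 36.1 and 37.2 CPM. Cholesterol synthesis had 1 of 15 (Dhcr7, 4.67, 4.70, 10.0 and 6.91 CPM). The cytokine (8 of 9), MHC class II (4 of 4) and complement (3 of 6) genes apart all lay within the free RNA level. Other genes of largest ratio were the glycosylation enzyme Galnt16 (32.5, 32.1, 0.237 and 0.391 CPM, 137-fold, 95% interval 46.4 to 669.7), the respiratory subunit Cox8b (126-fold, 95% interval 34.3 to 1044), Prr5, a subunit of mTOR complex (60.5-fold, 95% interval 10.5 to 2428), Hbb (54.3-fold, 95% interval 39.7 to 76.4), the actin binder Cap2 (50.4-fold, 95% interval 8.85 to 2009) and Serpina11 (44.5-fold, 95% interval 11.9 to 374). The lipase Pnlip was highest in set 3 at 12.7 CPM with 0 UMIs in set 2 (at least 54.1-fold), and the quinone reductase Nqo2 (51.4-fold, 95% interval 8.82 to 2070.3) was not apart without its top cells. Without set 2, 564 genes lay apart in place of 864, and without the mixed cluster 18, 795 of the 864 were kept. Other list members apart were, above the free RNA level, Ankrd37, Apod, Ddit4, Egr2, Errfi1, Fosb, Gria2, Hspe1, Junb, Kdr, Klf4, Parp14, Slc16a1, Tap1, Tgfb2, Tgfbr2 and Vegfa, and within it Anxa5, Atf3, Btg2, C1qa, C1qb, C1qc, Ccl2, Ccl3, Ccl4, Cd68, Cd74, Cldn5, Ctsz, Cx3cr1, Cxcl2, Dusp1, Efnb2, Esam, Flt1, Hspb1, Ifit2, Il1b, Irgm, Isg15, Nfkbia, Nfkbiz, Nlrp3, Psmb9, RT1-Ba, RT1-Da, RT1-Db1, Slco1a4, Slco1c1, Spp1, Tek, Tnfaip3, Trem2, Tyrobp and Zfp36. Of these, TMM scaling ended the calls on Apod, Efnb2, Hspe1 and Slco1a4.

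**Figure D3:**
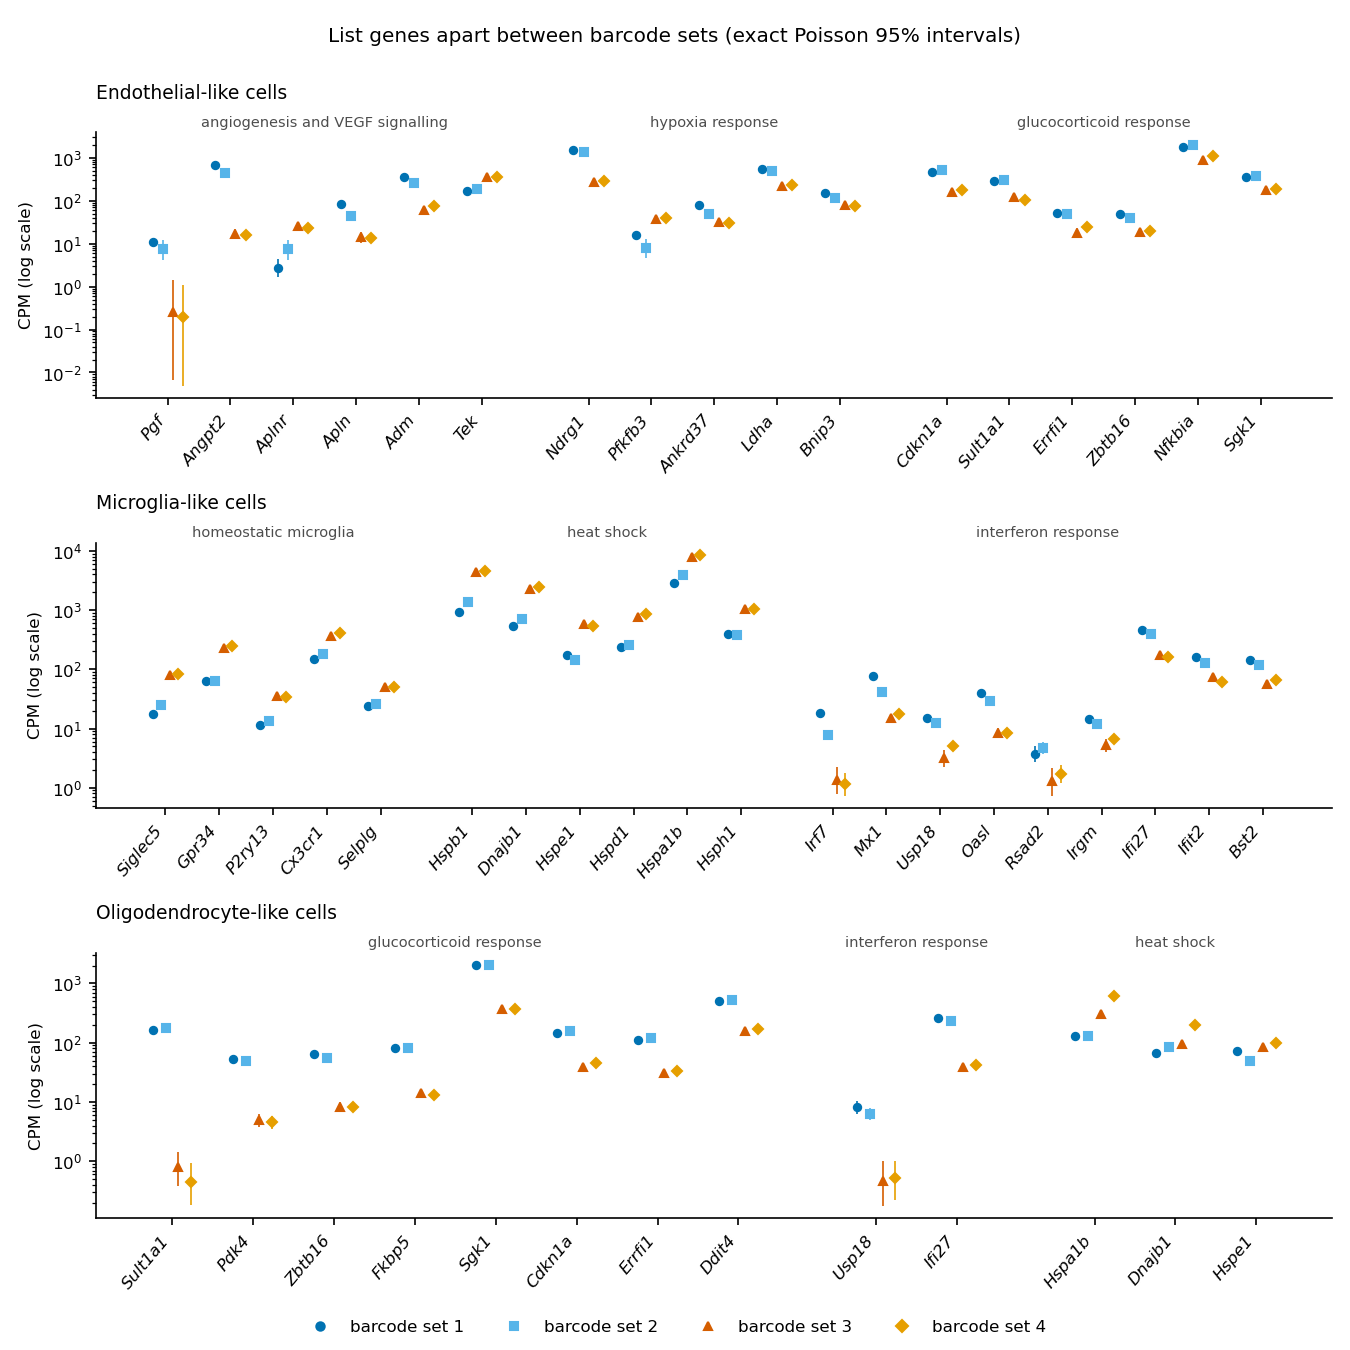
CPM (log axis) of part of the list genes that lay apart above the free RNA level between barcode sets 1 to 4 in endothelial-like, microglia-like and oligodendrocyte-like cells, 1 marker per set with exact Poisson 95% intervals that cover counting error only. Sgk1 ranged from 364 to 2038 CPM in oligodendrocyte-like cells and Irf7 from 1.15 to 18.3 CPM in microglia-like cells.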

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

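The alternatives without the doubtful clusters and without each gene's top cell were chosen after seeing the data; the other alternatives were chosen before the data were examined. No paired analysis was possible because each titled sample has 1 library and no barcode set is tied to a titled sample. The alternatives planned for differences between titled samples were not run for the same reason. Leaving out each set in turn shows what 1 library carries, and it is no replicate check. Of genes apart between sets, 5088 values under the alternatives stayed within the counting interval, 494 left it and 15 changed sign. Of the values of list genes in a class, 15804 stayed within the range over the sets and 687 left it. Of list medians 1532 stayed and 112 left it, with no called value changing sign. These tallies include alternatives that cannot move a value, so the numbers that stayed are no measure of stability. A lower ratio changes calls and no values. Other minimums of UMIs and marker members kept leave a list gene's ratio as it was. Without 1 set, the median over the remaining sets lies within the range over all sets by construction. Where a result below moved, the cause was not tested, except that thinning, a minimum of 200 UMIs and the stricter filter leave fewer UMIs or cells, and a lower ratio admits more genes. Depth limits which genes can be compared: of the 3506 cases of a gene apart between sets, 1206 still had the 50 UMIs needed after thinning to 1000 UMIs.

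Of all kept cells, endothelial-like cells made up 11.2%. The share of endothelial cells was 7.68% under the stricter filter, 10.6% with doublets kept, 10.4% with thinned cells, 10.7% without the doubtful clusters and 9.80 to 13.7% without 1 set. The share of microglia cells, 45.6%, was 39.7% with all barcodes, 52.9% under the stricter filter, 44.1% with doublets kept, 37.6% without the doubtful clusters and 42.5 to 47.5% without 1 set. The share of oligodendrocyte cells, 28.3%, was 24.9% with all barcodes, 23.2% under the stricter filter, 27.7% with doublets kept, 29.3% with thinned cells, 27.6% without the doubtful clusters and 26.4 to 30.7% without 1 set.

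Thinning left 785 genes higher in endothelial cells and 824 lower, 2273 genes lower in microglia cells and 1958 genes lower in oligodendrocyte cells, and 563 genes apart between barcode sets in endothelial cells and 517 in oligodendrocyte cells. TMM scaling gave 1848 genes higher in microglia cells in place of 1107. With a ratio of 1.5 the counts were 3072 genes apart between barcode sets in endothelial cells, 3542 genes apart between barcode sets in microglia cells and 2363 genes apart between barcode sets in oligodendrocyte cells, and with at least 200 UMIs 434, 694 and 346. Without 1 set, 564 (without set 2) to 695 genes lay apart in oligodendrocyte cells, 817 to 992 in endothelial cells and 1112 to 1319 in microglia cells. Of the 1193, 1449 and 864 genes apart, the stricter filter kept 719, 1300 and 513, thinning 277, 556 and 239, TMM scaling 852, 1207 and 785, and leaving out the doubtful clusters 1064, 1318 and 795. Thinning thus also brought in genes that had not lain apart (563 in endothelial cells, 277 of them among the 1193), and the cause was not tested. Of the 132, 156 and 192 calls on list genes in a class, TMM scaling kept 130, 145 and 192, the stricter filter 119, 148 and 181, the mean of per-cell CPM 124, 148 and 191, and thinning 98, 130 and 164.

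Signs changed in these genes (log2 of the highest over the lowest set). In endothelial-like cells, C3 was at -0.34 with the mean of per-cell CPM and -0.59 with thinned cells, Csf1r at -0.13 with doublets kept, Gja5 at -0.81 under the stricter filter and -0.63 without the doubtful clusters, and Nr2f2 at -0.15 and Trib3 at -0.12 with thinned cells. In oligodendrocyte-like cells, Ccl2 was at -0.47 with all barcodes, -0.43 under the stricter filter, -0.61 with doublets kept, -0.52 at resolution 0.5, -0.50 at resolution 2, -0.20 with the mean of per-cell CPM, -0.54 without the doubtful clusters and -0.46 without the top cells.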

Other observations

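The tests chosen only after the result was seen were those of depth per cell, of the top cells and of haemoglobin, and the counts of pairs and orders of sets, of genes in other classes and in unnamed clusters were chosen after the values were seen too.

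Some glucocorticoid-responsive genes differed between sets in cells outside the 3 focal classes as well, and others did not. Fkbp5, which dampens the glucocorticoid receptor, was at 112, 113, 31.6 and 36.0 CPM in T cell-like cells of sets 1 to 4. In border macrophage-like cells it was at 101, 82.0, 17.4 and 22.7 CPM, but with 18, 7, 3 and 16 UMIs, too few to count as measured. The kinase Sgk1 was lower in sets 3 and 4 in border macrophage-like cells (669.6, 339.7, 75.6 and 140.4 CPM), as in oligodendrocyte-like cells, and higher there in microglia-like cells (640.03, 736, 1169.7 and 1165 CPM), by less than the 2-fold needed to count as apart. Dusp1, a phosphatase, was at 1011, 1121, 374 and 470.4 CPM in T cell-like cells but at 2494, 2415, 2178 and 2509 CPM in pericyte-like cells. Klf9 ran the other way in T cell-like cells, at 36.5, 53.7, 106 and 79.3 CPM. In endothelial-like cells it did so too, at 157, 174, 304 and 291 CPM, but did not count as apart. Of the list members with enough UMIs, 3 of 9 lay apart in T cell-like, 2 of 6 in pericyte-like, 1 of 10 in smooth muscle-like and 6 of 6 in border macrophage-like cells. In the clusters named ependymal-like and monocyte-like, which mix cell types, these were 9 of 11 and 3 of 7. No share over all genes is given for these classes, so the counts have no baseline. Border macrophage-like cells were few (41, 23, 32 and 147 in sets 1 to 4). Not all their genes apart were lower in sets 3 and 4, since Cdkn1a was at 326, 562, 436 and 255 CPM. The genes shown were picked after their values were seen.

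The unnamed clusters held these transcripts. Cluster 13 (302, 184, 40 and 84 cells in sets 1 to 4) carried the endothelial markers Cldn5 (3196 CPM) and Flt1 (1434 CPM) along with haemoglobin, Hba-a2 at 138046 and Hbb at 87496 CPM; at resolution 2, 120 of its cells (65, 48, 3 and 4) formed a cluster named by the red cell list. Clusters 14 (190, 243, 56 and 162 cells) and 16 (50, 59, 11 and 14 cells) carried the plasma cell genes Mzb1 (3169.96 and 3616 CPM), Jchain (959 and 1021 CPM) and Ighm (3756 and 3769 CPM), for which no list was fixed. Cluster 17 (40, 11, 43 and 84 cells) carried endothelial and pericyte markers together, with Cldn5 at 4069 and Vtn at 788 CPM.

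The values of the 4 sets lay in 2 pairs. Between sets 1 and 2, 133, 178 and 127 genes lay apart in endothelial-like, microglia-like and oligodendrocyte-like cells, and between sets 3 and 4, 80, 62 and 41. Between sets 1 and 3 the counts were 568, 813 and 402, between sets 1 and 4 they were 682, 1003 and 458, between sets 2 and 3 570, 881 and 543, and between sets 2 and 4 665, 1001 and 519. Of the genes apart, 59.8%, 61.3% and 39.6% had their 2 highest values in sets 3 and 4, and 23.8%, 26.6% and 39.1% in sets 1 and 2, where 16.7% would follow if all orders were equally likely. Under TMM scaling these were 37.1%, 46.6% and 33.5%, and 42.7%, 40.1% and 45.9%. Which titled samples the sets are was not inferred.

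The first pattern weighed is the genes at least 2-fold apart between sets within a class, 3506 cases over the 3 classes, of which 93.4% still passed without each gene's top cell in each set. The top cell was taken from the lowest set as well, so a ratio could also grow. Without the top cells, 1248, 1448 and 875 genes lay apart in place of 1193, 1449 and 864. The 93.4% is therefore no measure of stability. A bias of the library that acts alike on a gene in every cell type could not be the whole cause, since of 5162 cases of a gene apart in a pair of sets 60.7% had ratios that differed between classes by more than 1 on the log2 scale with intervals that did not overlap, although 82 of the 91 genes apart in all 3 classes went the same way. Free RNA of other cell types stays open for a part: 80.4% of the cases differed by more than that of the named classes can bring, short of the 90% set beforehand. The unnamed clusters, such as cluster 13 with Hbb at 87496 CPM, were not counted as a source. The 80.4% can therefore be too high for transcripts of those clusters. Unequal depth per cell stays open as well, since 83.3% of the 1206 cases with enough UMIs kept a ratio of at least 2 after thinning to 1000 UMIs, short of the 90% set for that test. Library handling cannot be separated from animal or treatment, and no biological explanation was tested because no set is tied to a group.

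The second pattern is haemoglobin in all 3 classes. The ratio of Hba-a2 to Hbb UMIs in set 1 was 0.988, 1.29 and 1.19 in endothelial-like, microglia-like and oligodendrocyte-like cells, 1.30 times apart. Free haemoglobin RNA would give this, but red cells caught in the same droplets could too, so the ratio does not separate them. However, 30.9% of the 7381 Hbb UMIs lay in cells with at least 10 of them, over the 20% set for free RNA alone, so free RNA alone was not settled; red cells caught in the same droplets may add to it, which was not tested. No biological explanation was tested.

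The third pattern is neutrophil transcripts in endothelial-like cells of set 2. Of 563 S100a8 UMIs, 98.8% lay in cells with at least 10 of them, and this was 1 cell of 389, which argues against free neutrophil RNA. That cell held 556 S100a8 UMIs, and S100a9 and Mmp8 as well (100% of such cells, n of 1), and had 10979 UMIs against a median of 3346. A barcode that also holds a neutrophil is a candidate explanation, and Scrublet had not called it. No biological explanation was tested.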
